A study of Mus musculus with 6 samples.

How the data were processed

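Bone marrow-derived macrophages (BMDM) from C57BL/6/J mice aged 7 weeks were profiled by bulk RNA sequencing. Per the labels' protocols, marrow cells were grown with 20% L929-conditioned medium, which supplies macrophage growth factor, and were detached at day 6 and seeded at 800000 cells per well. At 6 h after seeding they received cancer cell-conditioned medium that either held its lipids or lacked them. The growth protocol states the culture time unclearly, mixing hours and days, so day 6 and 6 h rest on the treatment protocol alone. RNA was taken with a column kit and libraries were made with a stranded poly(A) kit, per the labels. The cancer cell line, the way lipids were removed and the length of exposure are not given in the sources used here.

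The authors deposited a table of raw counts per Ensembl gene for each of the 6 libraries. The submitters' processing notes name TopHat2 2.1.0, HTSeq, DESeq2 and the build GRCm38.p4, without saying which step used which tool, and versions of HTSeq and DESeq2 are not given in the sources used here. The strand setting and the annotation release behind the counts are likewise not given in the sources used here, so a gene and a partner on the opposite strand cannot be separated with certainty. Each table held 46603 gene rows, with 0 rows for unassigned reads. Gene names, coordinates, GC content and exon lengths came from GENCODE M21 on GRCm38, where 46091 identifiers matched and 512 did not. Unmatched identifiers stayed in the library totals and held 0.129% to 0.142% of counts.

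Libraries held 19429022 to 25323053 counts. At that depth 3 counts, the limit that a count of 0 allows, corresponded to 0.118 to 0.154 counts per 1000000 (CPM), a limit that covers counting error only. Groups were taken from the sample titles, with 3 libraries in each. Nothing in the labels says that replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. Replicates of a group differed by more than sampling noise, and all 6 libraries were kept. The spread was larger without lipids, where libraries correlated with each other at 0.992 to 0.995, against 0.996 to 0.997 with lipids. For each gene the fit used a dispersion shared by both groups.

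Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr (minimum count 10, minimum total 15), trimmed mean of M-values (TMM) factors scaled the libraries, and a quasi-likelihood F test compared the groups, two-sided, with Benjamini-Hochberg adjustment over 12767 genes and a threshold of 0.05. Log2 fold changes are with lipids minus without lipids, so positive values are higher with lipids. Standard errors (SE) came from the F statistic, and CPM values are given as mean ± SD over 3 libraries.

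Gene lists were fixed before the data were examined. They numbered 30, and 26 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists. The p with a correlation estimated for each list is given beside each call. Named genes followed a rule fixed at the same time. Its first part took the 8 largest changes in each direction among protein-coding genes with an official symbol past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between groups. The second part took up to 3 members of each called list, by smallest p, and the third was a fixed panel of lipid, stress and activation genes. Some genes of that panel are not reported here. Other genes named as examples from the fixed lists were chosen after their values were seen.

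The edgeR steps were tested on simulated counts for this comparison over 12767 genes. They recovered 24% of 50 genes changed 1.25-fold, 74% of 50 changed 1.5-fold, 86% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 14 false calls among 156. In a separate simulation camera called the single shifted list and 0 of 29 others. Genes there were drawn independently and lists were random, so false calls from correlated members of a list were not tested. Both simulations gave each gene the same dispersion in both groups. Recovery and false calls under the larger spread seen without lipids were therefore not tested.

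Alternatives fixed before the data were examined were median-of-ratios scaling, library totals without TMM factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, totals without the 20 most abundant genes, each library left out in turn, an adjusted p of 0.01, a test against a 1.5-fold change, an estimated list correlation and the fry rotation test. A correction for GC content and gene length, on 12720 genes, was added after seeing the data.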

Results

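RNA sequencing measured the transcripts of mouse macrophages grown from bone marrow and exposed to medium conditioned by cancer cells. In 3 libraries the medium kept its lipids and in 3 it lacked them. The comparison asked which macrophage transcripts changed with the lipid content of that medium. Totals were 21589789, 25323053 and 20778651 counts with lipids and 19429022, 19498289 and 22330119 counts without lipids.

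With lipids in the medium, macrophages held less transcript of most members of a preset lysosome list and of the fatty acid-binding proteins Fabp4 and Fabp5, and more of the mannose receptor gene Mrc1. Fabp4 was at 12.3 ± 1.3 CPM with lipids and 69.9 ± 2.0 CPM without (SD, n = 3 each), a log2 fold change of -2.50 (SE 0.09, edgeR adjusted p = 1.53e-07). Mrc1, which encodes CD206, was higher with lipids by 0.75 log2 (SE 0.05, edgeR adjusted p = 1.49e-05). Of 32 lysosomal genes tested, 25 were lower with lipids and 0 higher (camera adjusted p = 1.08e-27, adjusted p = 0.0566 with an estimated correlation). Across all genes 585 were higher and 877 lower with lipids among 12767 tested with edgeR's quasi-likelihood test at an adjusted p of 0.05.

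Most changes were small. The median size among the 1462 genes past the threshold was 0.44 log2, and at least 2-fold changes were seen for 47 genes higher and 89 lower with lipids. Groups did not overlap for 30.5% of tested genes, where chance gives 10%. Scaled by library totals alone, 1241 genes were higher and 596 lower, so the share higher went from 40.0% to 67.6% while the median of all tested genes moved to 0.07 log2. Leaving out replicate 1 of the group without lipids gave 1566 higher and 1975 lower genes. Without replicate 1, 2 or 3 of the group with lipids, the counts were 263 and 474, 219 and 423, and 243 and 488, and without replicate 2 of the other group they were 244 and 482. In a principal component analysis the first component (48.6% of variance) separated the groups, and replicate 1 without lipids lay at -22.96 on the second (21.8%), where the others lay between -1.17 and 13.95.

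Genes named for the size of their change were the 8 largest in each direction among protein-coding genes with at least 5 CPM in the higher group and no overlap between groups. Ppbp, a platelet chemokine gene on chromosome 5 (90768518 to 90770063, GRCm38), was at 11.4 ± 1.1 CPM with lipids and 2.81 ± 0.30 CPM without, a log2 fold change of 2.02 (SE 0.13, edgeR adjusted p = 1.08e-05). F13a1, the A chain of coagulation factor XIII, on chromosome 13 (36867178 to 37050244), was higher by 1.83 (SE 0.13, edgeR adjusted p = 1.75e-05). Lifr, the receptor for leukaemia inhibitory factor, was higher by 1.47 and reached 47.3 ± 2.0 CPM. Dmpk, a protein kinase, was higher by 1.39, from 27.9 ± 5.9 to 72.9 ± 3.7 CPM. Stxbp6 was higher by 1.64, Pilrb1 by 1.40, Lrrc4 by 1.24 and Nid2, a basement membrane protein, by 1.18. Pilrb1 has a close copy, Pilrb2, which was higher by 0.90, and reads of the pair may be shared. Lrrc4 and Nid2 overlap Snd1 and Rtraf on the other strand, which held 18283 and 12839 counts against 523 and 1232, so both values are uncertain if counting ignored strand.

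Among those lower with lipids, Dio2, an enzyme that activates thyroid hormone, on chromosome 12 (90724552 to 90738438), was at 1.26 ± 0.16 CPM with lipids and 11.3 ± 2.6 CPM without, a log2 fold change of -3.15 (SE 0.21, edgeR adjusted p = 1.08e-05). Fabp4 lies on chromosome 3 (10204088 to 10208576). Kit, the stem cell factor receptor, changed by -2.03 and Acod1, which makes the antimicrobial metabolite itaconate, by -1.89. Stra6l changed by -1.86, Gpr162 by -1.64, Cd22, an inhibitory lectin, by -1.62 and Mcoln3, a lysosomal cation channel, by -1.61. All 16 genes had edgeR adjusted p-values between 1.53e-07 and 0.000877. The lack of overlap between groups was a condition of their choice.

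**Figure D1:**
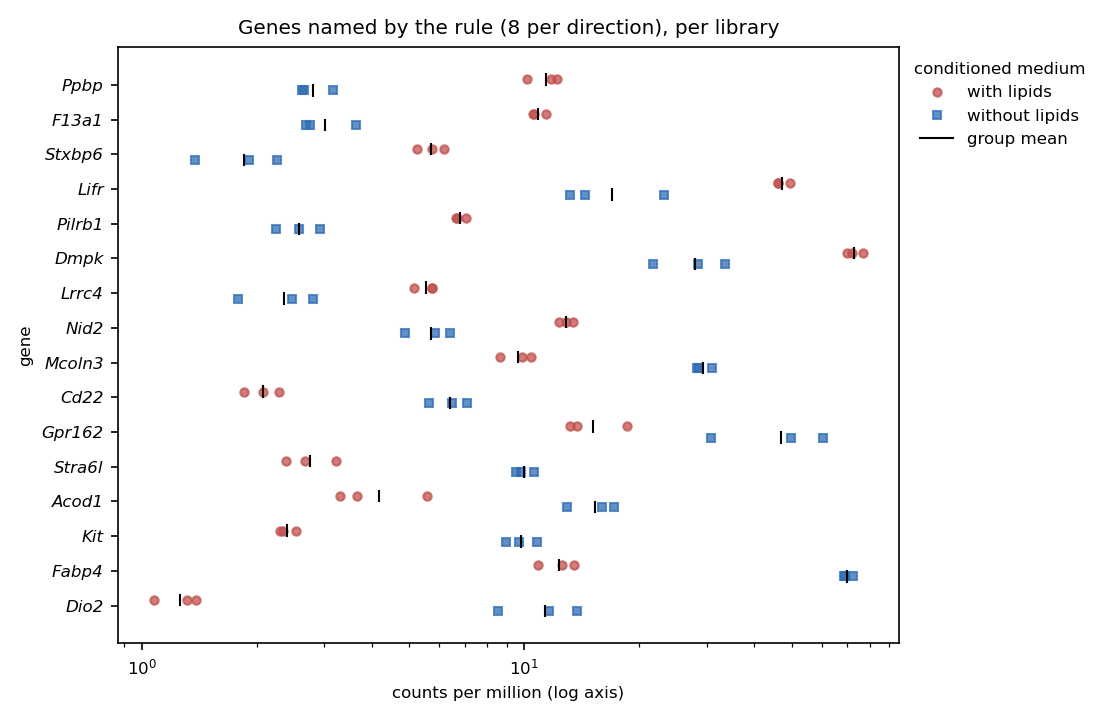
CPM on a log axis for 16 protein-coding genes, the 8 largest changes in each direction past the threshold with at least 5 CPM in the higher group and no overlap between groups, 1 point per library (3 per group), with a bar at each group mean. Dio2 is at 1.26 CPM with lipids against 11.3 CPM without.

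The lysosome list showed the lowest camera p of the 26 lists. Of its 32 members 25 were lower with lipids, 27 when adjusted over the list alone, and 30 had a negative log2 fold change (median -0.37, adjusted p = 0.0566 with an estimated correlation). Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, on chromosome 4 (19876841 to 19922605), was at 42.1 ± 0.9 CPM with lipids and 120 ± 9.2 CPM without, a log2 fold change of -1.51 (SE 0.07, edgeR adjusted p = 1.92e-06). Ctsz, a cathepsin protease, changed by -0.83 and Gla, alpha-galactosidase A, by -0.52. Ctsb and Ctsd, cathepsins among the most abundant transcripts, changed by -0.53 and -0.48. Ctsl, a member of the list that was also among them, did not pass the test at 0.11 (edgeR adjusted p = 0.356). Ctsz overlaps Nelfcd on the other strand. The 20 most abundant genes took 11.5 ± 0.11% of counts with lipids and 14.0 ± 0.42% without, a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow.

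The inflammatory list was called as lower with lipids. Of 29 tested inflammatory cytokines and NF-kB targets, 13 were lower and 1 higher, and adjusted over the list alone 15 and 2 (median -0.30, camera adjusted p = 1.31e-06, adjusted p = 0.275 with an estimated correlation). Tnfaip3, a brake on NF-kB signalling, changed by -0.95, Tnf by -0.90, the chemokine Cxcl2 by -0.82 and Tnfaip2 by -0.80. The member that was higher was Cd86, a co-stimulatory surface molecule, at 0.57. Il1b did not pass the test at -0.22 (SE 0.20, edgeR adjusted p = 0.523), and Nos2 lay below the filter with 1 or 2 counts per library. Over the fits that left out a library, 11 to 16 members of the list were lower and 1 or 2 higher.

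Of the stress-response lists, the PERK-ATF4 list was called as lower with lipids. Of 34 PERK-ATF4 targets 10 were lower with lipids and 0 higher, and 11 were lower adjusted over the list alone (median -0.17, camera adjusted p = 0.00073, adjusted p = 0.408 with an estimated correlation). The count of lower members was 2, 3 and 4 without replicate 1, 2 or 3 of the group with lipids, 2 without replicate 2 of the other group, and 5 with library totals alone, with list medians between -0.16 and -0.09. It was 14 and 13 without replicate 1 or 3 of the group without lipids, and 1 member was higher without replicate 1 of that group, with library totals alone, without the filter and after the GC and length correction. Atf3 changed by -0.73, Ppp1r15a by -0.60, Trib3 by -0.81 and Ddit3, also called CHOP, by -0.39. The call for Ddit3 was lost with library totals alone (edgeR adjusted p = 0.0562), and the gene overlaps Mars on the other strand. The IRE1-XBP1 list was not called, with 2 of 28 members lower, Edem1 and Edem2, and 0 higher (camera adjusted p = 0.893). Its calls were 3 higher and 1 lower with library totals alone, 2 and 2 without the filter, 6 and 3 without replicate 1 of the group without lipids, 1 and 2 without replicate 3 of that group or after the GC and length correction, and 0 higher with 0 or 1 lower in the other 4 fits that left out a library. Xbp1 was at 0.15 (SE 0.06, edgeR adjusted p = 0.151), but passed with library totals alone (edgeR adjusted p = 0.0368) and after the GC and length correction (edgeR adjusted p = 0.0478). Of 20 ATF6 targets and chaperones 1 was higher, Pdia4, against 3 with library totals alone or without replicate 1 of the group without lipids and 0 in the other 5 fits that left out a library, and Hspa5, the chaperone BiP, was at 0.05 (SE 0.06). Camera's direction for the ATF6 list was up while its median and mean were just under 0 (adjusted p = 0.876). Whether the branches differed from each other was not tested.

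The NRF2 antioxidant list was also called as lower with lipids. Of 23 members 10 were lower and 0 higher, and 13 were lower adjusted over the list alone (median -0.27, camera adjusted p = 1.05e-07, adjusted p = 0.138 with an estimated correlation). Fth1, the ferritin heavy chain that stores iron, changed by -0.67, Gstm1, a glutathione transferase, by -0.79, and Sqstm1, an autophagy receptor, by -0.50. Some other enzymes of the list, chosen after their values were seen, did not pass the test, with Gclc at 0.09, Nqo1 at 0.07, Hmox1 at 0.02 and Gclm at -0.04. Slc7a11 counted in this list and in the PERK-ATF4 list. Over the fits that left out a library, 7 to 15 members of the NRF2 list were lower and 0 or 1 higher.

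Lipid-handling lists held few called members. In the list of PPAR targets and lipid droplet genes 3 of 24 members were lower, Fabp4, Fabp5 at -1.33 and Plin2, which coats lipid droplets, at -0.54, and Pdk4 was higher at 0.72, a call lost with DESeq2 and in each fit that left out a library with lipids or replicate 2 of the other group. Its camera adjusted p was 4.98e-05 (adjusted p = 0.222 with an estimated correlation), and its median of -0.05 turned to 0.02 with library totals alone. Cd36, a fatty acid transporter, was at 0.04 (SE 0.08, edgeR adjusted p = 0.786). Of 23 cholesterol genes regulated by SREBP2, 2 were lower, Mvd at -0.64 and Lss at -0.32, and 21 had negative values (median -0.18, camera adjusted p = 0.00485, adjusted p = 0.804 with an estimated correlation). The call for Lss was lost with library totals alone (edgeR adjusted p = 0.0618). The number of lower cholesterol genes was 12 without replicate 3 and 5 without replicate 1 of the group without lipids, 1 in each of the other 4 fits that left out a library, 7 without the filter and 6 after the GC and length correction. Of 11 LXR targets 3 were lower, Nr1h3 at -0.68, Mylip at -0.49 and Smpdl3a at -0.38 (camera adjusted p = 0.0146, adjusted p = 0.657 with an estimated correlation). That list's call was lost without replicate 3 of the group without lipids (adjusted p = 0.181), and Abca1, at 0.09 (SE 0.12, edgeR adjusted p = 0.682), passed without it (0.0373). Without replicate 1 of that group, 6 LXR targets and 5 PPAR and lipid droplet genes were lower, and 6 LXR targets without the filter. Adjusted over each list alone, the counts for these 3 lists were those over all genes.

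Cell cycle genes formed the only called list that was higher with lipids. Of 40 members 9 were higher, 20 adjusted over the list alone, and 38 had positive values (median 0.34, camera adjusted p = 1.29e-08, adjusted p = 0.781 with an estimated correlation). Bub1b was higher by 0.40, Birc5 by 0.37 and Kif11, a spindle motor, by 0.46. Libraries without lipids were spread, with list scores of 0.12, -0.17 and -0.44 log2 against 0.20, 0.18 and 0.11 with lipids. The number of called members was 36 without replicate 1 of the group without lipids, 6 without replicate 3, and 0 in each of the other 4 fits that left out a library, where the list median stayed between 0.33 and 0.36. Camera called the list in all 6 of these fits (largest adjusted p = 0.00011, without replicate 3 of the group without lipids). The number of called members was 18 with library totals alone, 28 without the filter and 16 with DESeq2.

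The nuclear-encoded oxidative phosphorylation list was lower by a small amount. Of its 40 members 39 had negative values with a median of -0.11, but only Atp5k at -0.32 and Sdhc at -0.20 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.408 with an estimated correlation). With library totals alone the list median was only -0.03 and 0 members passed, so the size of the shift depended on the scaling. Sdhc stayed at -0.20 without the filter but did not pass (edgeR adjusted p = 0.0707), where 4 members passed, as with DESeq2. Atp5k did not pass after the GC and length correction (edgeR adjusted p = 0.168). Without replicate 1 of the group without lipids 12 members were lower, and 0 or 1 were lower without replicate 2 of that group or when a library of the group with lipids was left out.

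**Figure D2:**
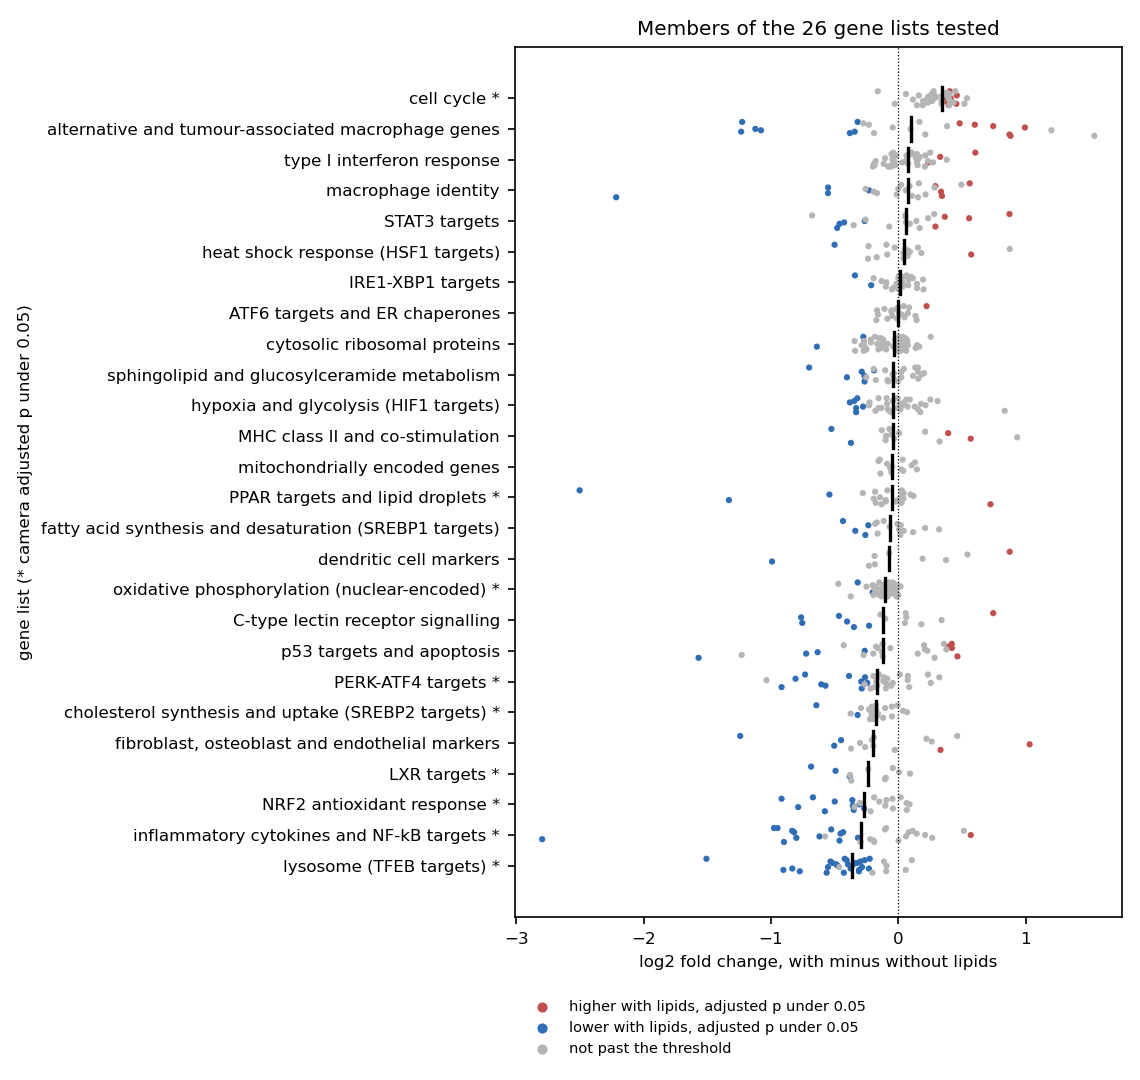
Log2 fold change (with minus without lipids) of each member of the 26 lists tested, 1 point per gene, with a bar at each list's median and an asterisk at the 9 lists called by camera at the preset correlation. The lysosome list has the lowest median, -0.37, and the cell cycle list the highest, 0.34.

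Alternative and tumour-associated macrophage genes moved both ways. Of 23 tested, 6 were higher and 7 lower with lipids, and 9 and 7 adjusted over the list alone (camera adjusted p = 0.903). In each fit that left out a library with lipids or replicate 2 of the other group, 5 were higher and 4 lower. Its median of 0.10 and mean of 0.08 were positive while camera's direction was down. Mrc1, on chromosome 2 (14229392 to 14332057), Cd163, a haemoglobin scavenger receptor, at 0.88, and Il4ra, the interleukin-4 receptor chain, at 0.87 were higher. Gpnmb at -1.23, the checkpoint ligand Cd274 at -1.23 and the elastase Mmp12 at -1.08 were lower. Arg1, arginase 1, was higher by 0.995 (SE 0.24, edgeR adjusted p = 0.023) at only 1.31 ± 0.21 CPM, and DESeq2 did not call it (adjusted p = 0.101).

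Among C-type lectin receptor genes, 6 of 14 were lower and 1 higher (camera adjusted p = 0.271). The lower count was 3 without replicate 1 or 3 of the group with lipids and 8 without replicate 1 of the other group, where 2 were higher, as they were without replicate 3 of that group, without the filter and after the GC and length correction. Clec4e, also called Mincle, changed by -0.75, Clec4d by -0.35 and the kinase Syk by -0.23, and the member that was higher was Mrc1. Of 20 STAT3 targets 4 were higher and 4 lower (camera adjusted p = 0.876), and 2 and 3 in each fit that left out a library with lipids or replicate 2 of the other group. Stat3 itself, which overlaps Stat5a on the other strand, was higher by 0.29 (edgeR adjusted p = 0.0316), and Socs3 was at 0.17 (edgeR adjusted p = 0.554). Of 26 sphingolipid genes 6 were lower, among them Psap at -0.70 and Degs1 at -0.40, and 0 higher (camera adjusted p = 0.151). With library totals alone 3 were lower and 3 higher, and after the GC and length correction 7 and 2. Leaving out replicate 1, 2 or 3 of the group with lipids gave 2, 3 and 2 lower, and leaving out replicate 1 of the other group 10 lower and 3 higher. Of 40 type I interferon genes 3 were higher, Oas2, Ifi204 and Ifi44, and 0 lower (camera adjusted p = 0.0717). The number higher was 11 with library totals alone, 8 without replicate 1 of the group without lipids, with 2 lower, and 1 in each fit that left out replicate 2 of that group or a library with lipids. After the GC and length correction 4 were higher and 2 lower.

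The remaining lists were not called. Of 35 hypoxia and glycolysis genes 6 were lower and 0 higher (camera adjusted p = 0.539), and of 17 fatty acid synthesis genes 4 were lower, Fasn among them, and 0 higher (0.333). With library totals alone these lists had 3 higher and 4 lower, and 1 and 1. Leaving out replicate 1 of the group without lipids gave 3 higher and 8 lower hypoxia genes and 1 higher and 6 lower fatty acid synthesis genes, while leaving out replicate 2 of that group gave 0 and 1 lower and leaving out replicate 1, 2 or 3 of the group with lipids 1, 1 and 0 lower hypoxia genes and 2, 1 and 1 lower fatty acid synthesis genes. After the GC and length correction 2 fatty acid synthesis genes were lower. MHC class II and co-stimulation had 2 higher and 2 lower of 14 (0.81), heat shock genes 1 and 1 of 17 (0.876), and p53 and apoptosis genes 4 and 4 of 25 (0.903). With library totals alone the counts were 2 and 1, 3 and 1, and 7 and 3, without the filter 2 and 2, 2 and 2, and 7 and 5, and without replicate 1 of the group without lipids 2 and 2, 4 and 1, and 6 and 8. The other 5 fits that left out a library gave 1 to 3 higher and 1 lower MHC class II genes, 0 to 2 higher and 1 lower heat shock genes, and 2 to 5 higher and 2 to 4 lower p53 genes. Camera's direction was up for the MHC class II list, whose median was -0.04 and mean 0.08, and for the p53 list, whose median was -0.12 and mean -0.10. Of 48 ribosomal protein genes 2 were lower, Rps14 and Rplp1 (0.266), against 20 without replicate 1 of the group without lipids, 9 without the filter, and 0 with library totals alone and in the other 5 fits that left out a library. Among 13 mitochondrially encoded genes 0 were called (0.903), and these took 1.67 ± 0.08% of counts with lipids and 1.63 ± 0.07% without.

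Macrophage identity genes moved both ways, with 4 of 22 higher and 4 lower (camera adjusted p = 0.665, up, with median 0.07 and mean -0.05). The counts were 7 and 3 with library totals alone, 8 and 7 without the filter, 7 and 7 without replicate 1 of the group without lipids, and 2 and 3 without replicate 2 of the group with lipids. Itgam was higher by 0.56, while Marco, a scavenger receptor, changed by -2.22 and Mpeg1 by -0.55. Despite its size, the change of Marco did not meet the criteria for the largest changes, which include at least 5 CPM in the higher group. Of 9 dendritic cell markers Irf4 was higher at 0.88 and Itgax lower at -0.99 (camera adjusted p = 0.935, down, with median -0.07 and mean 0.04), and 3 were lower without replicate 1 of the group without lipids. Of 15 fibroblast, osteoblast and endothelial markers 2 were higher and 3 lower, among them Vwf at -1.24 (camera adjusted p = 0.152), and 1 was higher and 6 lower without replicate 1 of the group without lipids. Leaving out a library of the group with lipids gave 0 higher and 1 or 2 lower. The lists of monocyte and neutrophil, lymphocyte, erythroid and megakaryocyte, and cancer cell markers had 3, 3, 3 and 2 tested members and were too small to test. In them Ccr2 was higher at 0.72, Csf3r lower at -0.70, Cd4 lower at -1.16, and Kit lower at -2.03, while Pf4, a platelet chemokine, was higher at 0.83 and Ppbp at 2.02.

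**Figure D3:**
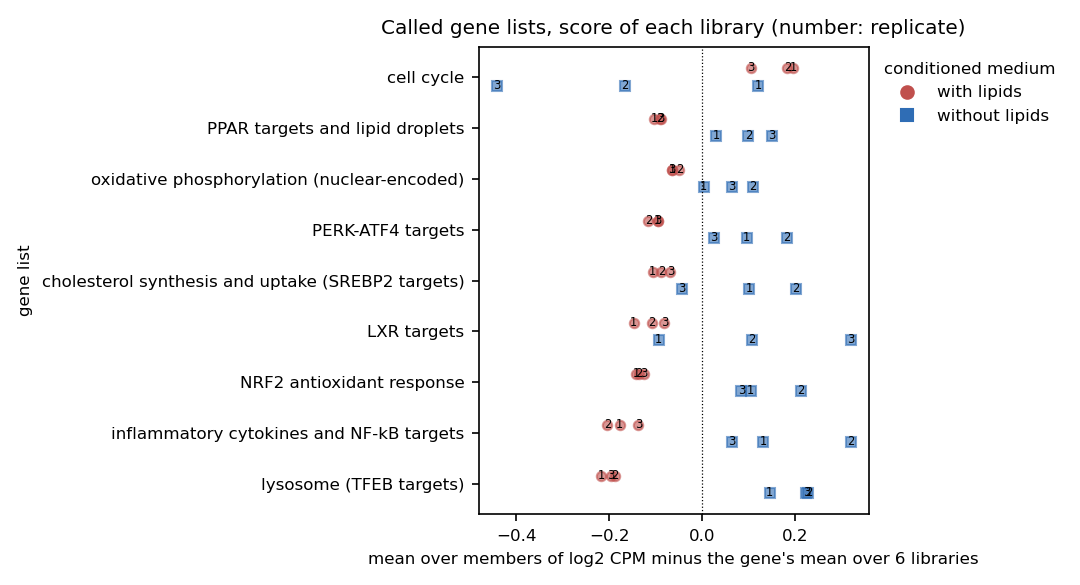
Score of each library for the 9 called lists, the mean over members of log2 CPM minus each gene's mean over 6 libraries, with the replicate number in each point. Lysosome scores lie between -0.22 and -0.19 with lipids and between 0.15 and 0.23 without, while cell cycle and LXR scores of the groups overlap.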

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

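All alternatives except the GC and length correction were chosen before the data were examined. Both counts of genes were within 1.5 times of 585 higher and 877 lower with median-of-ratios scaling, the stricter filter, DESeq2, limma-voom and totals without the 20 most abundant genes. The count of higher genes was 1241 with library totals alone and 1009 without the filter. At an adjusted p of 0.01 the counts were 216 higher and 444 lower, and in the test against a 1.5-fold change 25 and 64. Leaving out a library gave 219 to 1566 higher and 423 to 1975 lower genes. Where no cause is named, the cause was not tested.

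The replicate number was tried as a block. Deviations of same-numbered libraries correlated at -0.01, -0.09 and 0.18, and not every library correlated best with its own number. These values showed no pairing for every number, but with 3 libraries per group they cannot exclude one. The block gave 715 higher and 937 lower genes, and turned the direction of the uncalled p53 list (adjusted p = 0.887). Sdhc did not pass with it (adjusted p = 0.0754), and it called 25 cell cycle, 5 ribosomal and 0 ATF6 genes, and 7 macrophage identity genes as higher.

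With an estimated correlation the adjusted p was 0.804 for cholesterol, 0.657 for LXR, 0.222 for PPAR, 0.408 for PERK-ATF4, 0.275 for inflammatory, 0.408 for oxidative phosphorylation, 0.781 for cell cycle, 0.138 for NRF2 and 0.0566 for lysosome genes, so 0 of 9 calls held. Fry gave 0.197 for cholesterol, 0.186 for LXR and 0.218 for cell cycle genes. The other called lists passed with fry, at 0.00186 for lysosome, 0.00775 for PPAR, 0.0112 for NRF2 and 0.0254 for inflammatory genes. It gave 0.033 for both PERK-ATF4 and oxidative phosphorylation genes, and 0.0254 for sphingolipid genes. Sphingolipid genes were also called without the filter (0.0355) and after the GC and length correction (0.0289). Interferon genes were called with library totals alone (0.0301) and without the filter (0.0319). The direction turned for uncalled lists: mitochondrially encoded genes with library totals alone (0.975), p53 without the filter (0.941), and IRE1-XBP1 (0.849) and dendritic (0.814) genes after the GC and length correction. That correction also turned Hspa5 to -0.00065 and Cd36 to -0.0550.

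With a library left out, list p-values ranged from 0.000274 to 0.181 for LXR, 0.0177 to 0.217 for interferon, 0.0011 to 0.665 for ribosomal and 0.00775 to 0.245 for fibroblast genes. The ribosomal and fibroblast lists were called only without replicate 1 of the group without lipids, and the interferon list also without replicate 3 of the group with lipids. Ranges where the direction turned were 0.460 to 0.983 for IRE1-XBP1, 0.156 to 0.937 for MHC class II, 0.598 to 0.991 for STAT3, 0.503 to 0.974 for alternative macrophage, 0.731 to 0.974 for dendritic, 0.460 to 0.917 for heat shock, 0.156 to 0.715 for macrophage identity, 0.643 to 0.891 for mitochondrially encoded and 0.708 to 0.983 for p53 genes. Abca1 ranged from -0.0283 to 0.281 and Cd36 from -0.0320 to 0.144. Calls were lost in 5 of the 6 such fits for Ddit3, in 4 for Lss, Sdhc, Bub1b, Birc5, Kif11, Arg1 and Stat3, in 3 for Atp5k, in 2 for Trib3 and in 1 for Mylip. Depth limits Arg1 and Il1b, at under 2 CPM.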

Other observations

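All gene families and tests in this part were chosen after the results were seen. Of 40 families defined by gene symbol, 38 had at least 4 tested genes, and p-values are adjusted over those 38. Subunits of the V-ATPase, the lysosomal proton pump, were lower with lipids for 12 of 18 and higher for 0 (median -0.30, camera adjusted p = 1.57e-12, adjusted p = 0.0462 with an estimated correlation), and 6 of the 18 also belong to the lysosome list. With library totals alone 11 were lower and 1 higher, and without replicate 2 or 3 of the group with lipids 7 and 8 were lower. Of 24 lysosomal hydrolases only 6 were lower and 0 higher (median -0.17, camera adjusted p = 0.0115, adjusted p = 0.451 with an estimated correlation). For these the lower count was 2, with 1 higher, with library totals alone, 2 in each fit that left out a library with lipids or replicate 2 of the other group, and 14 without replicate 1 of that group. Atp6v1c1 changed by -0.57 and Atp6v1g1 by -0.50. Ctsc, a cathepsin that activates other proteases, was higher by 0.95 while 6 of 12 cathepsins were lower. The cathepsin family was called as lower (camera adjusted p = 0.00026, adjusted p = 0.263 with an estimated correlation), and 6 of the 12 also belong to the lysosome list.

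Surface receptor families moved in different directions. Of 8 Ms4a genes 6 were higher, led by Ms4a4a at 1.03, and Ms4a7 was lower at -0.46 (camera adjusted p = 0.000196, adjusted p = 0.451 with an estimated correlation). Without replicate 1 or 2 of the group with lipids 4 Ms4a genes were higher and 0 lower. Of 9 chemokine receptors 4 were higher, among them Ccr3 at 1.01, Ccr2 at 0.72 and Ccr1 at 0.51. The 3 that were lower were Ccrl2 at -1.10, Cxcr4 at -0.64 and Cxcr3 at -0.54. Camera called this family as higher (median 0.50, camera adjusted p = 0.0104, adjusted p = 0.263 with an estimated correlation). In the SLAM family of immune cell receptors 4 of 7 genes were lower and 0 higher, Slamf8 by -1.54, Slamf7 by -0.98, Ly9 by -0.88 and Cd48 by -0.26 (camera adjusted p = 1.4e-06, adjusted p = 0.181 with an estimated correlation). Gadd45a and Gadd45b, stress-induced growth arrest genes, changed by -1.12 and -1.22.

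The lower level of lysosome genes with lipids was set against 3 technical explanations. If a few abundant genes had taken the counts, such genes would hold a larger share with lipids, yet the 17 of the 20 most abundant genes outside the list held 8.72 ± 0.10% with lipids and 10.6 ± 0.32% without, a difference of -1.84 percentage points that was negative in all 9 pairs of libraries. Some of the 17, such as Gpnmb and Psap, were themselves lower with lipids, and the share of all 20 was already known. That comparison is therefore not independent of the pattern. After the GC and length correction, which raised the calls to 840 and 1198, the list's median was -0.32 against -0.37. In the 6 fits with a library left out the median was never closer to 0 than -0.34. Between 18 and 27 members were lower in these fits, and 0 or 1 higher. With library totals alone the median was -0.29 and 22 members were lower. A lysosomal response to the lipid content of the medium may account for the pattern, as a hypothesis, but anything else that lipid removal changed in the medium stays open and untested.

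The higher level of cell cycle genes with lipids is less settled. The difference of mean list scores was 0.32 log2, with an exact two-sided permutation p of 0.2, where 0.1 is the smallest possible. Without replicate 3 of the group without lipids the difference was 0.18, too little to tell whether that library carried it. The 2 explanations therefore cannot be told apart with 3 libraries per group. GC content and gene length did not account for it, since the list's median was 0.337 after that correction and 0.343 before. A difference in division with the lipid content of the medium may also be present, and was not tested apart from the spread between libraries.

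Higher Ppbp, Pf4 and F13a1 with lipids could come from platelets, megakaryocytes or monocytes in the cultures. Gp9, Gp1bb and Itga2b, abundant in platelets or their precursors, summed to 3.92% of the 791 Ppbp counts with lipids (upper 95% limit 5.61%), and Gp9 and Gp1bb together to 1 count. The rest were Itga2b, at 30 counts with lipids and 17 without. Pf4 held 28691 counts with lipids and 13861 without, against 791 and 167 for Ppbp, so Pf4 was abundant in both groups. No ratio of Gp9, Gp1bb or Itga2b to Ppbp or Pf4 in platelets was measured here. The values alone therefore cannot exclude platelets or megakaryocytes. Over all 20 monocyte and neutrophil markers the summed counts per library total had a ratio of 1.20 with over without lipids (95% limits 1.15 and 1.24), carried by Ccr2, while the 17 below the filter had 69 and 87 counts, a ratio of 0.718 (0.516 to 0.996). Limits cover counting error only, the 17 lie near the floor, and Csf3r was lower, so monocytes stay open. A change within macrophages also stays open, as a hypothesis.

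The count of genes past the threshold was compared with other splits of the 6 libraries. The real split gave 1462 genes and the highest of the others 0, and 1 of the 10 splits reached the real value, which is too few splits for a share under 0.05.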
